A study of Mus musculus with 14 samples.

How the data were processed

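The series holds ChIP-seq of 13 transcription factors in Hoxb8-FL cells of the mouse, with 1 library per factor, and 1 rabbit IgG library, for which no peak list was used here. Per the labels' protocols, fixation lasted 10 min in formaldehyde at 0.4% or at 1% (which factor had which is not given in the sources used here), chromatin was sonicated for 7 min with 30 s on and 30 s off, and DNA was precipitated with an antibody against 1 factor. Libraries followed the Illumina TruSeq kit, per the labels' protocols. Per the submitters' processing notes, Bowtie2, MACS2 and bedtools were used and the builds were mm10 and GRCm38. Their versions, the roles of the tools, the calling threshold and the use of the IgG library in calling are not given in the sources used here.

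The deposited lists hold positions of peaks, in base pairs on mm10, in 3 columns (chromosome, start and end), with no score, height or read count. Every peak is 400 bp wide, no list holds a duplicate line, and the meaning of the order of the lines is not stated. Depth is therefore unknown. It can change how many peaks a library gives, so list lengths were not compared as amounts of binding. The common width sets how far apart midpoints can lie and still count as overlapping. Lists were analysed on 19 autosomes and chromosome X, which left out 3 lines on the mitochondrial genome (1 of Cebpa and 2 of Cebpb). Coordinates in the text count from 1.

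Genes came from a RefSeq gene table of the assembly GRCm38.p6, the build of the files, with 21627 protein-coding genes on these chromosomes. It has the lower and upper boundary of each gene and neither strand nor exons, so a distance is to either boundary and exons, introns and untranslated regions were not told apart. "Below" and "above" a gene mean lower and higher coordinates. Gene boundaries took the place of transcription start sites wherever the planned design named these. No genome sequence was used here. For that reason the planned search for sequence motifs was not run, nor was the planned look-up of published enhancers by distance from a start site, with their alternatives.

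Regions were made by merging all peaks that touched or overlapped by 1 bp or more. A peak was alone if it overlapped no peak of the other 12 lists. For a pair of lists, the peaks of the shorter list that overlapped the longer by 1 bp or more were counted, with the Ochiai similarity, an odds ratio and the partial correlation of presence over the merged regions. Observed values stand beside 100 random placements (20 for location), in which each peak moved to a random place on its chromosome between the first and last position seen there. Gaps of the assembly were not excluded, and placement was not limited to accessible chromatin. A peak was near a gene boundary if its midpoint lay within 1 kb of one. For the heptad, the number expected from independent lists is the product of the shares of merged regions, and all 924 sets of the same size with, or without, Gata2 were ranked.

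A locus was the gene body with 50 kb either side. Lists of genes were fixed for the factors assayed, other blood stem cell regulators, stem and multipotent progenitors, granulocytes and monocytes, B cells, T cells, erythroid cells, megakaryocytes and platelets, mast cells and basophils, housekeeping, liver, neuron, and heart and skeletal muscle. Of 250 entries 249 were found. Some genes are in more than 1 list, 10 of the other regulators for instance. Each list's value has its percentile among 10000 random lists of protein-coding genes of the same size, matched on decile of locus length. Neighbours in a list, such as Rag1 and Rag2, share most of a locus and were counted as separate genes. Random genes were drawn without regard to neighbours, so percentiles of lists with neighbours can be too extreme. Percentiles describe these libraries and are not p-values across replicates, and a list outside the central 95% of the random lists was called high or low.

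Gene lists, the main settings and most alternatives were chosen before the data were examined, as was the rule for the genes and regions named. The rule took all 13 factor genes, the 3 genes of every other list with the most factors in the locus (ties by more peaks, then by alphabet), and the 10 genes genome-wide nearest to the region with the most factors (ties by more regions with 10 or more factors, then by alphabet). It also took the 5 regions with the most factors (ties by smaller span), the 4 pairs of related factors and each factor's closest partner. Some genes taken by the rule are not reported here. Other factor pairs and combinations of list and factor in the text were picked after their values were seen.

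Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and neither a second culture nor a second immunoprecipitation. Alternatives changed the merging, the overlap, the boundary window, the locus, the random lists and the similarity measure, and left out the Spi1 list or peaks near boundaries. Those that need a score (the top 50% of peaks, lists shortened by score) were replaced by the order of lines in the files. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated lists and on the real peaks. In 4 simulated pairs of lists, the recovered overlap missed the planted one by at most the random overlap plus 0.182 percentage points. The 121980 merged regions of the real peaks matched those of bedtools 2.31.1 in number and start. With the real peaks, 4% of 200 random gene lists passed the 95th percentile.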

Results

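Binding of 13 transcription factors was mapped by ChIP-seq in Hoxb8-FL cells, a mouse line of multipotent haematopoietic progenitors held in culture by a conditional Hoxb8 protein and Flt3 ligand and labelled as resembling lymphoid-primed multipotent progenitors. The factors were Cebpa, Cebpb, Erg, Fli1, Gata2, Gfi1, Gfi1b, Lmo2, Lyl1, Meis1, Runx1, Spi1 and Tal1. Each was represented by 1 library and 1 peak list, so no difference between factors had a replicate check and no p-values were computed. The series title places the maps beside models of the blood stem cell regulatory network, and the questions asked of them here were which regions and which genes the factors shared. Read depth was unknown, because the lists give positions without counts or scores.

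Spi1 (PU.1), an ETS factor required for myeloid and lymphoid development, had by far the longest list, with 76378 peaks. Cebpb and Cebpa, C/EBP factors of the granulocyte and monocyte lineage, followed with 37795 and 35065 peaks. The bridging protein Lmo2, which binds DNA through partners, had 26738 peaks, the ETS factor Fli1 had 22034 and the basic helix-loop-helix factor Tal1 had 17193. The homeobox factor Meis1 had 13736 peaks, Runx1 had 11728, the zinc finger repressor Gfi1 had 9482, Erg had 9014, the Tal1 relative Lyl1 had 8903 and Gfi1b had 8675. Gata2, a zinc finger factor of stem cells, had the fewest, 3217.

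Lists also differed in how many of their peaks overlapped a peak of any other factor. Only 0.326% of Lyl1 peaks (95% interval 0.218 to 0.467) and 0.499% of Erg peaks (0.364 to 0.667) stood alone. Fli1 had 3.64% alone, Runx1 5.18%, Gfi1 7.28%, Lmo2 7.90%, Gfi1b 9.21%, Cebpa 9.40%, Cebpb 12.3% and Tal1 17.9%. Meis1 had 41.5% alone (40.6 to 42.3), Spi1 58.5% (58.2 to 58.9) and Gata2 70.4% (68.8 to 72.0). With peaks placed at random on the same chromosomes, 95.8% to 97.4% of each list stood alone. In every list the peaks in the first 50% of the lines were shared more often than those in the rest. The share alone was 0.384% against 35.5% for Tal1, 17.1% against 65.8% for Meis1 and 63.1% against 77.7% for Gata2. Differences in list length can come from the antibody, the depth and the calling threshold as well as from binding.

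**Figure D1:**
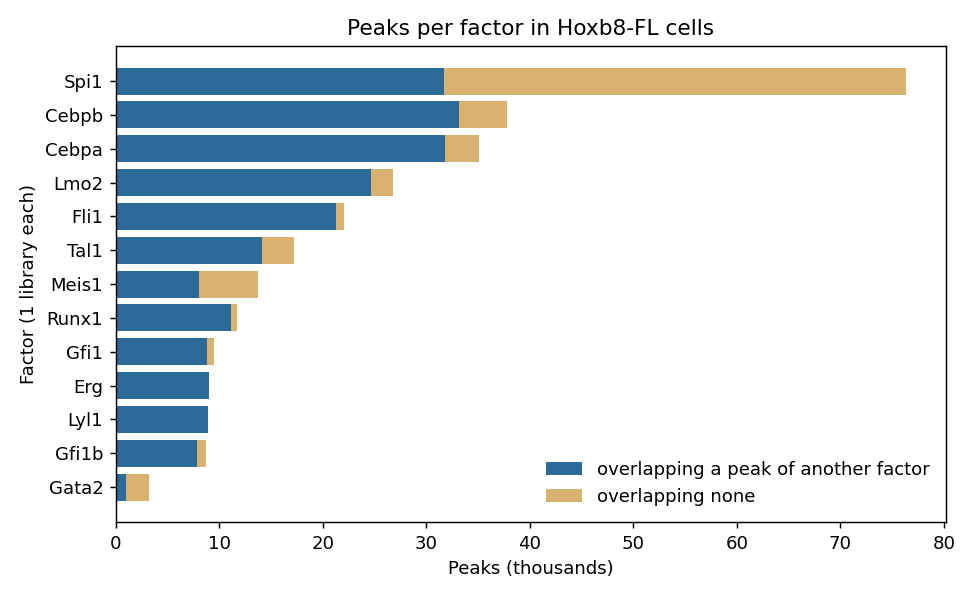
Number of peaks (horizontal axis), 1 library per factor (vertical axis), split into peaks that overlap a peak of another factor and peaks that overlap none. Gata2 had the shortest list and the highest share of peaks alone, 70.4%.

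Merging all 279955 peaks gave 121980 regions, of which 53252 (43.7%, 95% interval 43.4 to 43.9) held peaks of 2 or more factors. Random placement gave 3.89% ± 0.0335 (SD over 100 placements) and never more than 5 factors in a region. Of the 68728 regions with a single factor, 44679 held Spi1. At the other end, 2831 regions (2.32%) held 10 or more factors, 573 held 12 and 41 held all 13. Gata2 was the missing factor in 515 of the 573 regions with 12. Regions with 10 or more factors had a median width of 542 bp, against 400 bp for regions with 1 factor.

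Lmo2, Fli1 and Tal1 were nearly always present in the regions with 10 or more factors, at 99.6%, 99.5% and 98.7% of them. Cebpb (97.8%), Cebpa (95.7%), Lyl1 (95.2%), Spi1 (93.3%) and Runx1 (90.4%) followed. Erg was present in 84.9%, Gfi1 in 84.2%, Gfi1b in 67.0%, Meis1 in 64.0% and Gata2 in 7.35%. Their number with Lyl1 equalled 30.3% of the Lyl1 list and that with Erg 26.7% of the Erg list, but that with Spi1 only 3.46% and that with Gata2 6.47% of the respective lists. Without the Spi1 list 1668 regions held 10 or more factors, and with only the first 50% of the lines of each file 987 did.

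The 5 regions with the most factors, by the smallest span among those with all 13, lay on 5 chromosomes of the mm10 (GRCm38) build. One was chr16 95439133 to 95439613, inside the Erg gene and 80.2 kb from its lower boundary. Another was chr10 41937147 to 41937618, inside Armc2, and a further one was chr19 40818689 to 40819150, inside Cc2d2b. The region at chr4 108349865 to 108350321 lay 9.37 kb outside Coa7, and that at chr2 53850779 to 53851232 lay 154 kb from the nearest protein-coding gene, Gm38481. Whether the regions inside genes were exonic or intronic was not analysed here.

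**Figure D2:**
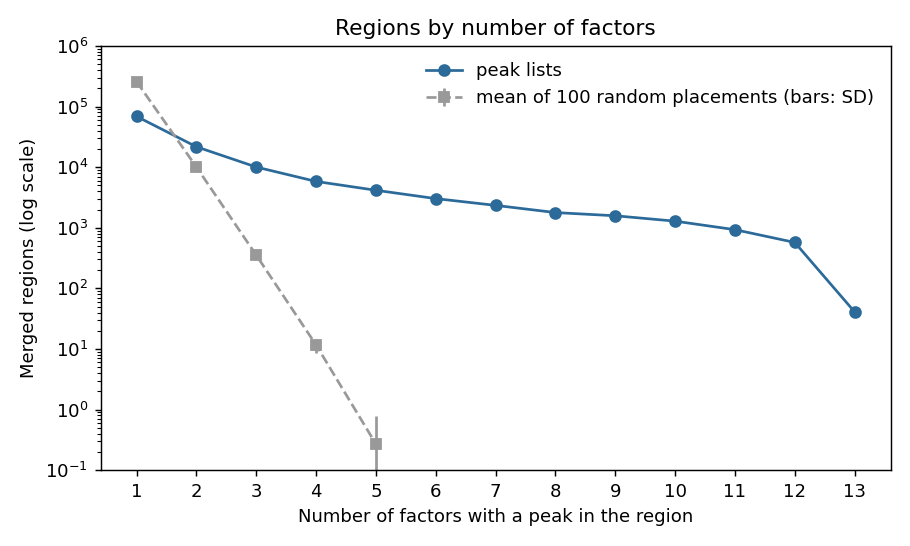
Number of merged regions (vertical axis, log scale) by the number of factors with a peak in them (horizontal axis). Observed regions reached 41 with all 13 factors, while random placement (mean of 100, bars SD) gave none above 5.

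By similarity of the whole lists, the 4 related pairs Cebpa and Cebpb, Lyl1 and Tal1, Gfi1 and Gfi1b, and Erg and Fli1 came first. The lead of Erg and Fli1 over the next pair was very small. Spi1, a more distant ETS factor, was not counted as related to Erg and Fli1. Of the Cebpa peaks, 82.4% (95% interval 82.0 to 82.8) overlapped a Cebpb peak, 67.0 times the number from random placement. Of the Lyl1 peaks, 91.4% (90.8 to 92.0) overlapped Tal1, 163-fold over random. For Gfi1b on Gfi1 the share was 68.8% (67.8 to 69.8), 215-fold over random, and for Erg on Fli1 it was 95.7% (95.2 to 96.1), 130-fold over random. By Ochiai similarity, which divides the shared peaks by the geometric mean of the list lengths, these pairs held ranks 1 to 4 of 78, at 0.793, 0.658, 0.658 and 0.612. Tal1 and Lmo2 (0.611) and Fli1 and Lmo2 (0.608) followed Erg and Fli1 too closely for rank 4 to be firm. The 4 related pairs also held ranks 1 to 4 by partial correlation over the merged regions, which holds the other 11 factors fixed. It was 0.651 for Cebpa and Cebpb, 0.588 for Gfi1 and Gfi1b, 0.445 for Lyl1 and Tal1 and 0.348 for Erg and Fli1. By share or fold alone they did not all come first, since 97.0% of Lyl1 peaks overlapped Lmo2 and Lyl1 on Erg was 168-fold over random. With each list shortened to the length of the Gata2 list, Erg on Fli1 fell to 59.0% and the closest partner of Lyl1 was Lmo2. By the Jaccard index, or without peaks near gene boundaries, the closest partner of Fli1 was Lmo2.

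By Ochiai similarity Lmo2 shared almost as much with Tal1 and Fli1 as the lowest related pair, Erg and Fli1 (0.612), did with each other. By partial correlation Tal1 and Lmo2 (0.277) and Fli1 and Lmo2 (0.240) lay below all 4 related pairs. Of the Tal1 peaks 76.3% overlapped Lmo2 (Ochiai 0.611), of the Fli1 peaks 67.0% did (0.608), and of the Lyl1 peaks 97.0% did (0.560). Runx1 was closest to Erg (0.503), with Fli1 (0.502) and Lmo2 (0.502) next to it, a difference too small to rank. Spi1 was closest to Fli1, with 77.6% of Fli1 peaks on a Spi1 peak (Ochiai 0.417), and Meis1 was closest to Lmo2 (0.284), with Lyl1 (0.274) near it. By partial correlation and with shortened lists the closest partner of Meis1 was Lyl1, and by the Jaccard index it was Tal1. All 12 pairs with Gata2 ranked last by Ochiai similarity, from 0.0738 with Fli1 down to 0.0272 with Meis1. By partial correlation their ranks ran from 23 with Lyl1 to 77 with Spi1. Of the Gata2 peaks 19.3% overlapped Fli1, 27.1-fold over random. No pair of lists lay below the 7.53-fold of Gata2 on Spi1, so an excess over random does not mark out a pair.

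The 5 most negative partial correlations of all pairs involved Spi1. With the other factors held fixed, they were -0.195 with Meis1, -0.191 with Gata2, -0.159 with Cebpb, -0.116 with Tal1 and -0.109 with Cebpa, while Fli1 (0.149) and Lyl1 (0.130) had positive values. Spi1 overlap was still above random for these factors, 7.53-fold for Gata2, 16.7-fold for Meis1 and 18.0-fold for Cebpb. A negative value over merged regions arises in part because every region holds at least 1 peak, and Spi1 alone fills 44679 of them.

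**Figure D3:**
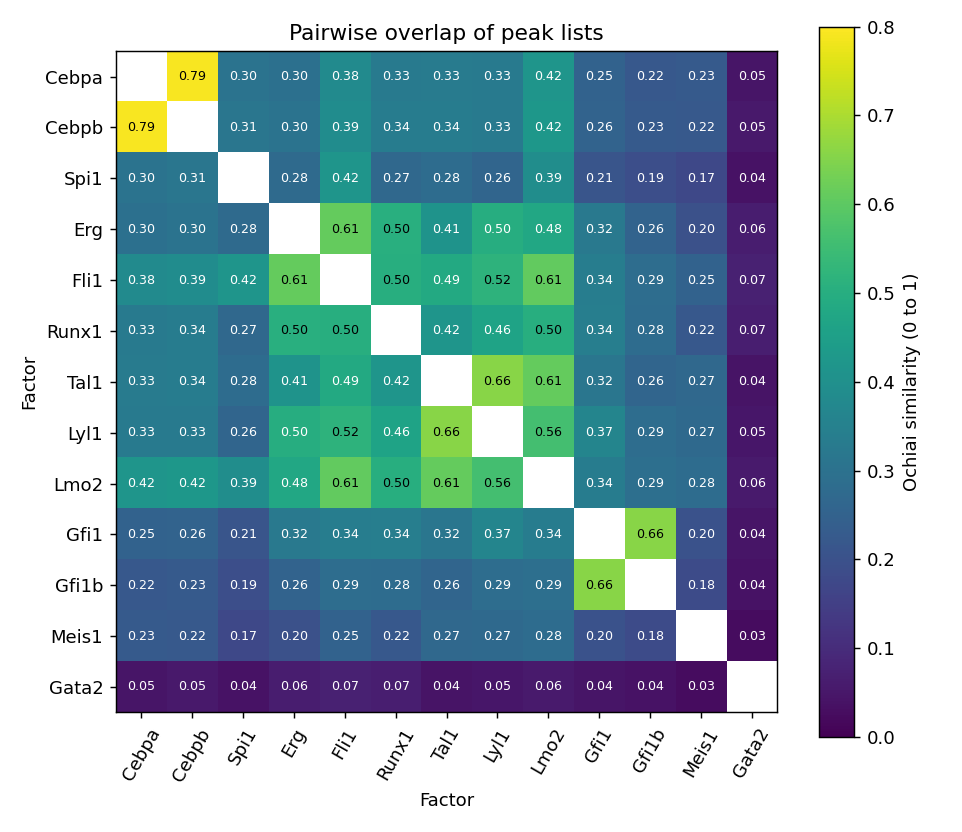
Ochiai similarity (colour scale from 0, and printed values) for each pair of the 13 peak lists, factors on both axes. The 4 related pairs had the highest values, from 0.612 to 0.793, with Tal1 and Lmo2 close behind at 0.611, and Gata2 had the lowest.

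Tal1, Lyl1, Lmo2, Gata2, Runx1, Erg and Fli1 form a set of 7 factors, often called the heptad, known to bind together in blood stem and progenitor cells. In these lists 143 regions held all 7, while independent lists over the same regions would give 0.00928 and random placement gave 0. The 6 factors without Gata2 shared 3057 regions. Gata2 was present in 4.68% of these (95% interval 3.96 to 5.49), against 2.64% of all merged regions. The latter share counts the 70.4% of Gata2 peaks that stood alone, which cannot lie in a region with the 6. These shares are therefore not like for like.

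Other sets were shared as widely. Among the 924 sets of 7 factors that include Gata2, the heptad ranked 52 by number of regions, and the median set had 86. The largest, with 200 regions, joined Cebpa, Cebpb, Fli1, Gata2, Lmo2, Lyl1 and Tal1. Among the 924 sets of 6 factors without Gata2, the heptad members ranked 42 by number and 26 by observed over expected. The largest set of 6, with 5052 regions, was Cebpa, Cebpb, Fli1, Lmo2, Spi1 and Tal1. With the first 50% of the lines of each file, 54 regions held the heptad.

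Runx1, Erg and Fli1 bound near gene boundaries most often, and Meis1, Tal1 and Lyl1 least. Within 1 kb of the start or end of a protein-coding gene lay 28.8% of Runx1 peaks (95% interval 28.0 to 29.7), 26.5% of Erg peaks (25.6 to 27.4) and 22.7% of Fli1 peaks (22.1 to 23.3). Gfi1 had 17.5%, Lmo2 15.7%, Gfi1b 15.7%, Gata2 13.8%, Cebpb 12.8%, Cebpa 12.4% and Spi1 11.4%. Lyl1 had 7.36% (6.82 to 7.92), Tal1 5.81% (5.47 to 6.17) and Meis1 4.80% (4.45 to 5.17). Random placement gave close to 3.1% for each list, so that Runx1 was 9.09-fold and Meis1 1.57-fold above it.

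The location of a region also went with the number of factors in it. The share near a gene boundary was 8.57% for regions with 1 factor, 15.4% for 2 to 3 and 22.3% (95% interval 21.59 to 23.02) for 4 to 6, and then 12.2% for 7 to 9 and 6.29% (5.42 to 7.25) for 10 to 13. The fall was not seen within either part when regions were split by whether they held Tal1, Lyl1 or Meis1, the 3 lists with the fewest peaks near boundaries. Regions with none of these lay near a boundary in 35.3% of cases (34.0 to 36.6) with 4 to 5 of the other 10 factors and in 50.5% (43.3 to 57.7) with 8 to 10. Regions with 1 or more of the 3 did so in 6.99% and 7.21%. This split, chosen after the values were seen, also sorts regions by location. The start and the end of a gene were not told apart, because the gene table used here has no strand.

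**Figure D4:**
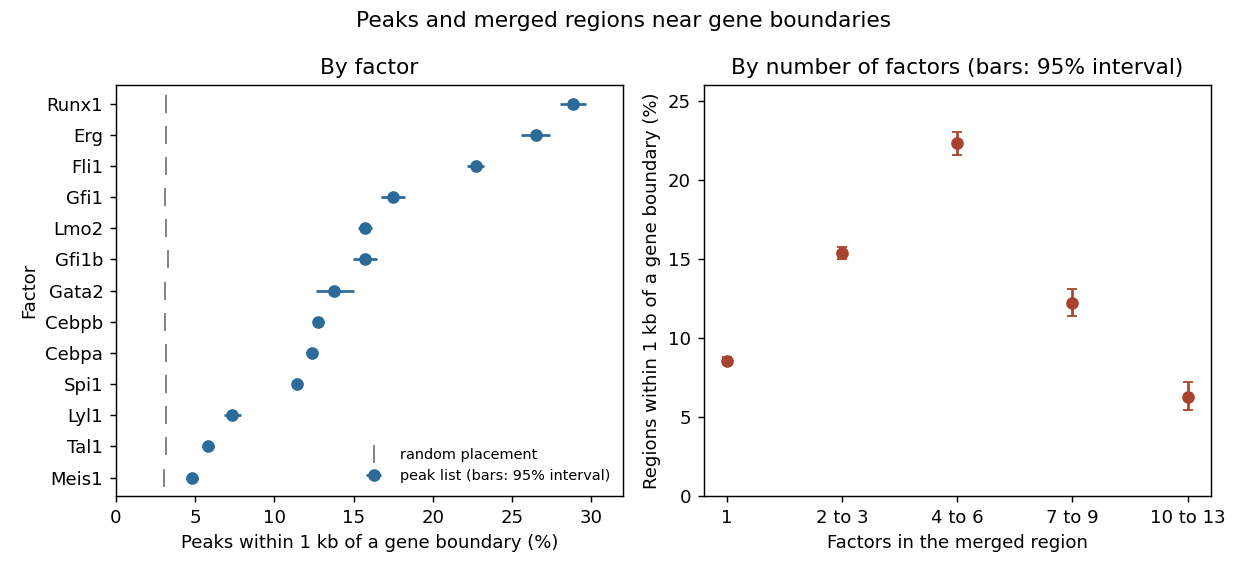
Left, peaks within 1 kb of a gene boundary (%, horizontal axis) for each factor, with the random value. Right, the same share of merged regions by number of factors, highest for 4 to 6 factors at 22.3% and 6.29% for 10 or more (bars are exact 95% intervals).

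The genes of the 13 factors were bound by nearly all of the factors. A factor had a peak in the gene body or within 50 kb of it for 157 of the 169 combinations of factor and factor gene (92.9%). Random lists of 13 genes of like locus length had 99.3 on average, with 70 to 126 as the central 95% and 148 as the highest of 10000 lists. Each of the 13 factors had a peak at its own gene. Over all protein-coding genes, the share of loci with a peak ran from 23.2% for Gata2 to 84.7% for Spi1. Of the 12 combinations without a peak, 7 were Gata2 at Cebpb, Gfi1, Gfi1b, Lmo2, Lyl1, Spi1 and Tal1. The others were Gfi1b at Lmo2, Gfi1 and Gfi1b at Tal1, and Meis1 at Lyl1 and Tal1. Without Gata2 peaks, 151 of 156 combinations were present.

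The Cebpa, Erg, Fli1, Gata2, Meis1 and Runx1 loci held all 13 factors, and the Tal1 locus held the fewest, 9. Runx1 had the most peaks in its locus, 217, and 7 regions there held 10 or more factors. At Cebpa a region with all 13 factors lay at chr7 35156439 to 35156939, 37.4 kb above the lower boundary of the gene. At Meis1 a region with all 13 lay inside the gene at chr11 18924580 to 18925323. Regions with 12 factors lay inside Runx1 at chr16 92800751 to 92801260, which lacked Lmo2, and inside the Spi1 gene interval at chr2 91096454 to 91096926, which lacked Gata2. At Gfi1b a region with 12 factors, again without Gata2, lay at chr2 28599155 to 28599767, and at Gfi1 another lay at chr5 107749488 to 107750028.

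At the Gata2 gene the most shared region, chr6 88166025 to 88166532, had 11 factors and lay 27.6 kb below the gene, but had no Gata2 peak itself. The Lyl1 gene had an 11-factor region at chr8 84699790 to 84700304, 1.38 kb below its lower boundary. Fli1 and Lmo2 each had a 10-factor region outside the gene, at chr9 32556263 to 32556719 and chr2 103945748 to 103946212. The most shared region at Tal1, with 9 factors, lay 0.446 kb inside the gene at chr4 115056486 to 115057260, and that at Cebpb, with 7 factors, at chr2 167710535 to 167711003.

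Genome-wide, the genes nearest to a region with all 13 factors and to the most regions with 10 or more were Runx1 (12 such regions), the zinc finger gene Zfp608 (10), the interferon regulatory factor gene Irf2 (5), Msrb3 (4) and Uaca (4). Abca1, a cholesterol transporter, Armc2, Gm41291, Meis1 and Pdhx had 3 each. Nearest regions can lie outside the 50 kb locus. The Runx1 and Zfp608 loci each held 7 regions with 10 or more factors, counted whichever gene was nearest to them. The 13-factor regions nearest to Runx1, Msrb3 and Abca1 lay outside the locus. So did all 4 regions with 10 or more factors nearest to Uaca, whose locus held only 6 factors.

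Gene lists of the blood lineages had more factors per locus than matched random lists, and so did housekeeping genes. Some lists hold neighbours that share most of a locus, such as Hoxa9 and Hoxa10, or Rag1 and Rag2. Random lists were not matched on this, so the percentiles can be too extreme. Stem and multipotent progenitor genes had a mean of 10.4 ± 2.80 factors (SD over 20 genes), against 8.08 in random lists (percentile 99.67). B cell genes had 10.7 ± 2.06 over 19 genes (99.98), megakaryocyte and platelet genes 10.3 ± 3.06 over 15 genes (99.965) and granulocyte and monocyte genes 9.20 ± 3.30 over 25 genes (99.1). Erythroid genes had 9.25 ± 2.71 over 20 genes (99.4), although with 10 kb either side of the gene they stood at percentile 59.0. The list of other blood stem cell regulators had 9.59 ± 2.91 over 29 genes (98.0). T cell genes (9.50, percentile 94.2) and mast cell and basophil genes (9.67, percentile 97.05) lay within the central 95% of random lists.

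Housekeeping genes had 10.55 ± 1.70 factors over 20 genes (percentile 99.995), within the range of the blood lists. Liver genes had 6.30 ± 3.26 (5.78), heart and skeletal muscle genes 7.75 ± 3.13 (63.5, but 5.61 with 10 kb and 92.2 with 100 kb) and neuron genes 6.25 ± 3.58 (1.66). The low place of neuron genes did not hold with 100 kb either side (percentile 3.97) or with random genes matched also on gene density (4.04).

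Values of single factors are given per list, and differences between lists were not tested. Meis1 had a peak at 19 of 20 stem and multipotent progenitor genes and 14 of 15 megakaryocyte and platelet genes, against 58.4% and 47.1% in random lists (percentile 100 for both). It also had one at 10 of 12 mast cell and basophil genes (99.2) and at 15 of 20 heart and skeletal muscle genes (99.5), but with 10 kb either side these stood at 94.1 and 86.4, and mast cell and basophil genes at 88.3 with 100 kb. Lmo2 had a peak at all 15 megakaryocyte and platelet genes (99.96). Tal1 had a peak at all 19 B cell genes (percentile 100) and Erg at 18 of them (99.995), while at the 20 housekeeping genes Tal1 had one at 16 (98.4, but 63.7 with 10 kb and 90.2 with 100 kb) and Erg at 18 (99.965). Cebpa and Cebpb each had a peak at 24 of 25 granulocyte and monocyte genes (99.8 and 99.7), and likewise at all 20 housekeeping genes (99.8 and 99.7) and all 16 T cell genes (98.9 and 98.5, but 89.4 and 94.9 with 10 kb and 95.1 and 94.5 with 100 kb). Gfi1 and Gfi1b each had one at 16 of 20 stem and multipotent progenitor genes (99.2 and 99.5), the latter at 92.9 with 100 kb.

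At the low end, Erg had a peak at 3 of 20 liver genes, against 56.0% in random lists (percentile 0.005). Runx1 had one at 5 (0.09, but 4.255 with 100 kb) and Lmo2 at 9 (0.42, but 19.7 with 10 kb and 4.405 with 100 kb). At neuron genes Erg had a peak at 6 of 20 (1.41, but 2.565 with 100 kb), Runx1 at 7 (1.14, but 4.78 with 10 kb and 3.115 without peaks near boundaries) and Fli1 at 10 (1.08). The low place of Fli1 was lost with 10 kb (4.955), 100 kb (9.215), matching on gene density (3.06) and without peaks near boundaries (12.7). Of the 169 combinations of list and factor, a nominal 2.5% would pass each bound by chance. The true share differs, because gene counts are small and some combinations cannot reach a bound. Spi1, with a peak at all 16 T cell genes, stood at only 91.7.

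The genes named here were picked as the 3 of each list with the most factors in the locus, so their counts are high by choice. All 13 had a peak at Flt3, the receptor for the ligand these cells grow in, and at the RNA-binding protein gene Msi2, where a region with all 13 lay at chr11 88608093 to 88609179. All 13 also had a peak at the neutrophil granule genes Mpo, Elane and Prtn3, and Elane and Prtn3 are neighbours that share a locus. The same held for Ebf1 of B cells, for Myb, Mitf and Nfe2 among other regulators, and for Bcl11a, a repressor of fetal globin. Itgb3 and Gp1ba of platelets and Il1rl1 and Mcpt4 of mast cells also had all 13.

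Gata2 was the factor missing at Blnk, Cd5, Tfrc, Zfpm1 and Mllt3, each with 12. The T cell kinase gene Zap70 had 12 factors without Meis1. In the lists of other tissues, Apoa2 had all 13, Camk2a, Syn1, Ryr1 and Tnni3 had 12, Dlg4 and Myl2 had 11, and Hpx and C8a had 10. Ywhaz and Eef2 among housekeeping genes had all 13 and Rab7 had 12. A peak within 50 kb of one of these genes can lie in or near another gene.

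**Figure D5:**
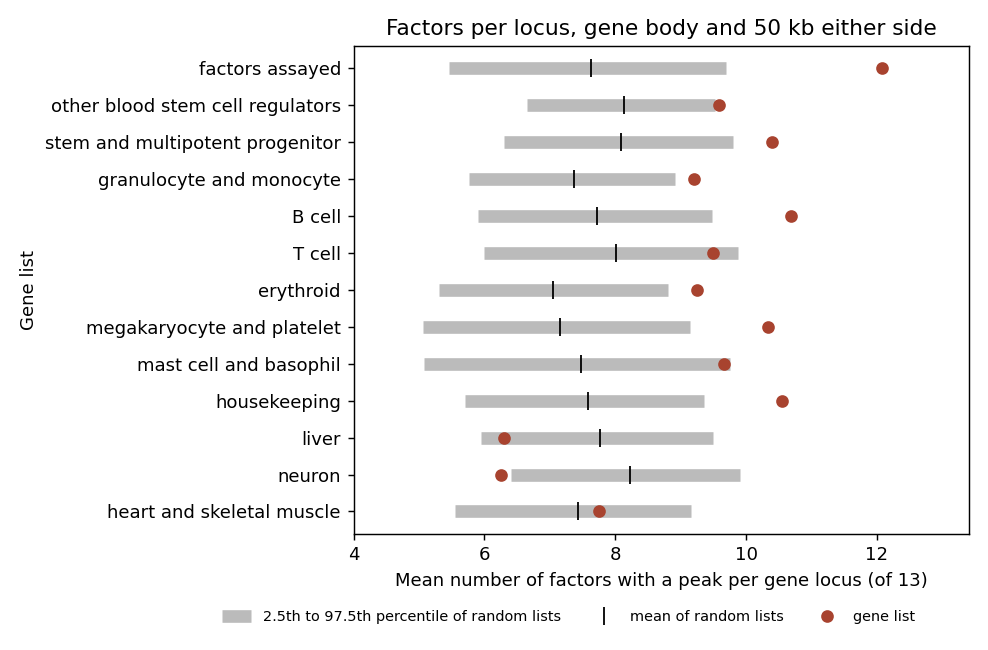
Mean number of factors with a peak per gene locus (horizontal axis, of 13) for the 13 gene lists (vertical axis), with the mean and the central 95% of 10000 matched random lists. The factor genes had 12.1 and neuron genes 6.25.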

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

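Alternatives that use the order of lines or leave out Gata2, and the gene lists without peaks near boundaries, were chosen after seeing the data. Regions with 2 or more factors, 43.7% of all, were 42.1% with 200 bp windows at the midpoints, 59.4% without Spi1, 41.5% without peaks near gene boundaries, 46.1% with the first 50% of each file and 44.3% without Gata2. Regions with 10 or more factors, 2831, were 1668 without Spi1 (10 or more of the 12 factors left, a stricter bound) and 987 with the first 50% of each file. Heptad regions, 143, were 54 with the first 50% of each file and 3057 as the 6 factors without Gata2. Cebpa on Cebpb was 81.8% with overlap of 50% or more, 80.2% with midpoints within 100 bp, 82.9% without peaks near boundaries and 83.8% with lists shortened to the length of the Gata2 list. Erg on Fli1 was 94.97%, 92.7% and, shortened, 59.0%. Gfi1b on Gfi1 was 65.9% with midpoints within 100 bp. Lyl1 on Tal1 was 89.2% with midpoints within 100 bp, 92.4% without peaks near boundaries and 79.5% shortened. The closest partner stayed the same for 9 to 13 of the 13 factors, 9 with shortened lists and with the Jaccard index, and Runx1, Lmo2, Fli1, Meis1, Lyl1 and Gata2 had another partner in at least 1 setting. The median share near a boundary over the 13 lists, 13.8%, was 10.4% at 500 bp and 18.3% at 2 kb, with the same 4 highest and 3 lowest factors. With 10 kb either side, T cell genes rose to percentile 98.1 and erythroid genes stood at 59.0, with Cebpa at erythroid genes at 46.2, on the other side of the middle. Neuron genes stood at 3.97 with 100 kb either side and 4.04 with matching on gene density, and mast cell genes at 99.8 without peaks near boundaries. Of 67 high or low combinations of list and factor, 48 kept their place with 10 kb and 46 with 100 kb. The number of factors moved by over 1.5 times at 12 of the named genes with 10 kb and at 0 with 100 kb. The latter says little, since a wider locus can only add factors. All named genes but Uaca already held 9 or more of the 13, too many for such a rise. The cause of these shifts was not tested. Pairs of factor and factor gene, 157, were 140 with 10 kb, 164 with 100 kb and 153 by nearest gene. Settings by peak score, motif content and known elements could not be run, and the depth that limits each list is unknown.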

Other observations

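The test of list length for Gata2 and the split of regions by Tal1, Lyl1 and Meis1 were chosen after the results were seen. Values in the first paragraphs were picked after looking at the data.

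Gata2 peaks differed in place with the number of factors beside them. Of the 951 that overlapped another factor, 38.9% (95% interval 35.8 to 42.1) lay within 1 kb of a gene boundary, more than in any whole list, and of the 277 in regions with 4 to 6 factors 58.1% did, but of the 208 in regions with 10 or more only 5.29% (2.67 to 9.27). Of the 2266 alone, 3.22% (2.53 to 4.03) did, against 3.11% for random placement of the list. Tal1 peaks alone (3.43%) and Meis1 peaks alone (3.30%) were as low, whereas Runx1 peaks alone had 53.9% and Fli1 peaks alone 42.8%. Chromosome X, 6.56% of the span analysed, held 3.36% of Gata2 peaks and 0.895% (Runx1) to 2.12% (Spi1) of the peaks of the other lists. The first 10 lines of the Gata2 file all lay on chr11 between 3152979 and 3193381. That stretch held 15 Gata2 peaks, and a wider window around it held 46 peaks of 4 other lists. Neither was checked against regions known for mapping artefacts.

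Within the regions with 10 or more factors, the midpoints of Tal1, Lyl1, Lmo2, Erg, Fli1 and Runx1 peaks lay close together. Over the 15 pairs among these 6 factors, the median distance ran from 17 bp (Lmo2 and Lyl1) to 31 bp (Runx1 and Tal1). Cebpa and Cebpb lay 16 bp apart, but each lay 41 to 58 bp from the other 10 factors. Spi1 lay 36 bp from Fli1 and 39 bp from Erg. Meis1 and Spi1 were the farthest of the 66 pairs without Gata2, at 61 bp.

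The first pattern is that 70.4% of Gata2 peaks overlapped no other list. The values of the other 12 lists argue against the length of the list by itself. When each of the other 12 lists was shortened to the same length from the end of its file, the lowest, Spi1, had 84.4% shared. Gata2 had 29.6%. In every list, however, earlier lines were shared more often than later ones, so the cut kept the more shared part of each list. The cut by itself therefore cannot separate length from the order of the lines. Uncut, the other 12 lists still had more of their peaks shared than Gata2, from 41.5% (Spi1) to 99.7% (Lyl1). Dropping lines without regard to their order would on average leave these shares as they are. The depth behind the Gata2 list is unknown. Background calls spread over the genome may account for the peaks alone, which lay within 10 kb of a region with 4 or more factors 1.19 times as often as at random (14.8% against 12.5%, highest of 100 placements 14.5%). That is just above chance but far below the 2.49-fold of Spi1 peaks alone and the 3.03-fold of Fli1 peaks alone, so background remains open for most of them, as it does for Meis1 (1.19-fold) and Tal1 (0.854-fold) peaks alone. No biological explanation, such as a low level of Gata2 protein, was tested.

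The second pattern is that midpoints of related factors lay closer together than those of other pairs. If this came only from stronger regions being shared, the distances should even out within the regions with 10 or more factors. There the median over the 4 related pairs was 19.5 bp against 43 bp over the 62 others, a ratio of 0.453. The bound set in advance, a related median below the lower quartile of every other pair, was not met, since the smallest of these was 8 bp and 6 unrelated pairs lay as close as the related ones. Closeness may thus go with the group of Tal1, Lyl1, Lmo2, Erg and Fli1 as much as with kinship, and shared motifs and antibody cross-reaction stay open as untested.

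The third pattern is that regions with 10 or more factors lay near gene boundaries less often (6.29%) than regions with 4 to 6 (22.3%). Lists poor in peaks near boundaries could fill these regions, and both bounds set in advance against this were met: without Tal1, Lyl1 and Meis1 the share was lower with 8 or more of the 10 factors left (10.5%) than with 4 to 5 (22.4%), and within all 12 lists without Gata2 it was lower with 10 or more factors than with 4 to 6, with separate intervals in 10. Neither removes the regions themselves, since 92.3% of those with 8 or more of the 10 factors held 1 or more of the 3. When regions were split, the share did not fall among those with none of the 3 (50.5%, 95% interval 43.3 to 57.7, with 8 or more of the other factors, against 35.3% with 4 to 5), but these 198 regions are those missed by lists that avoid boundaries. The explanation therefore stays open, and no biological explanation was tested.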
